A study of Mus musculus with 17 samples.

How the data were processed

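The samples were sorted naive CD4 T cells of mice, WT or lacking STAT4 or STAT6, grown for 7 days. Per the labels, Th1 cultures received interleukin 12 at 20 ng/ml for 3 days and then at 10 ng/ml with interleukin 2 at 50 U/ml for 4 days, with antibody against interleukin 4 at first. Th2 cultures received interleukin 4 at 10 ng/ml throughout, with antibody against interferon gamma at first and interleukin 2 for the last 4 days. Cells were stimulated again for 2 h and fixed with 1% formaldehyde, and libraries of about 250 bp were made with 18 PCR cycles and sequenced on an Illumina Genome Analyzer. There were 17 libraries: STAT4 in WT and STAT4-deficient Th1 cells, STAT6 in WT and STAT6-deficient Th2 cells, 3 histone marks in these 4 cultures, and normal rabbit serum in WT Th2 cells. The grouping was taken from the labels, and each group held 1 library.

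Each library came with a file of aligned reads, deposited as 1 line per read of 25 nucleotides with its position and strand, so the values used are read counts made here from these deposited reads. Per the submitters' processing notes the genome build was mm9 and the tool was SICER, which calls broad enriched regions. No version and no settings were stated, and the aligner is not given in the sources used here. The files show 2 kinds of alignment record. The 6 Th1 histone libraries hold match classes with up to 2 mismatches, still hold repeated reads at a position (2.58% to 5.97%), and have 49.0% to 66.4% of reads without a mismatch. The other 11 hold a mismatch string, have at most 1 read per position and strand, and have 90.2% to 97.6% of reads without a mismatch. For 13 libraries the authors also deposited values in 200 bp windows within enriched regions. In the 6 Th1 histone files this signal sums to about 1000000 over the windows, as found from the values, so it was taken as a signal scaled by the authors to the reads within enriched regions. In the 7 Th2 files the values are in rpm, reads per 1000000 of the total, per the file headers. The kinds of file differ in unit, so their values were not set against each other, and only windows were counted.

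Reads on the mitochondrial chromosome were left out, and the rest were counted once per position and strand, which left 5402414 to 12075444 reads per library. Each read was shifted by 75 bp towards the fragment centre. The mm9 sequence (NCBIM37) and the GENCODE vM1 annotation were used, with 22219 protein-coding genes that have a symbol. A table of current gene symbols served only to match synonyms. Every value of the marks is a ratio of 2 read counts, and a minimum of 20 reads in either library was asked of a gene, which limits which genes were measured. In simulated data with reads moved at 2, 3 and 5-fold, 19.4% to 50.7%, 83.6% to 95.5% and 95.5% to 100% of the changed genes were called (the call itself asks for 2-fold), with 0 to 4 unchanged genes called per comparison. Here and for the lists below, both simulated libraries were drawn from the same profile with counting error alone. Such numbers do not estimate false calls that come from differences in enrichment or between cultures.

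STAT-bound regions were found in 200 bp windows with a Poisson upper tail p under 1e-05 in the WT library (at least 7 reads), joined over gaps of up to 200 bp. A region was kept when the lower bound of the exact 95% interval of its WT to deficient ratio, scaled by total reads, was 2 or more. The rabbit serum library was counted in the same regions as a second control. The regions called with the libraries swapped were also counted. Such regions need more reads in the deficient library. Their number therefore does not count false regions that come from stronger enrichment of the WT library or from differences in chromatin between the cultures. With regions planted in a part of the deficient library, those of 15 reads were called in 82% of cases, of 30 reads in 99.5% to 100%, and 0 and 5 regions were called elsewhere. Both sides of that test came from the same library, so it holds no difference between libraries. A region belonged to a gene when it lay in the gene or within 10 kb upstream, and to a promoter when within 2000 bp of a start. Expected overlaps of regions came from shuffled regions. Numbers of genes expected if independent, here and for the marks, are products of the shares of genes in the 2 sets. They were not adjusted for gene length or read number.

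H3K4me3 was counted within 2000 bp of the gene start, H3K27me3 from 2000 bp upstream to the gene end, and H3K36me3 over the gene. Counts of a pair of libraries were scaled by the median ratio over measured genes. A gene was called lower or higher when its ratio was 2-fold or more and the exact 95% interval excluded 1.5-fold. No p-value was computed across genes, since each group was 1 library, and every interval covers counting error only, not differences between animals or cultures. Ratios against 0 reads are given as at least N-fold against a floor of 3 reads over the library. The 14 fixed lists were Th1, Th2, Th17 and Treg, follicular helper, naive and memory T cell, STAT feedback and cytokine signalling, pan T cell, housekeeping and interferon response genes, B cell, myeloid, natural killer and CD8 T cell, and erythroid and mast cell markers, and developmental Polycomb targets. Of their 266 entries 265 were matched to the annotation, Sox1 being the exception. The median log2 ratio of a list was compared with 10000 random lists of the same size matched on mean reads in 20 bins, for lists with 5 or more measured genes. In simulated data for the 3 H3K36me3 comparisons 5 to 7% of unchanged lists fell outside that range, and the other marks were not simulated in this way. With 14 lists and 9 comparisons, some lists lie outside their range by chance. Genes with a STAT region were compared in the same way.

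The lists, the comparisons, the thresholds and the rule for named genes were chosen before the data were examined. That rule named Stat4, Stat6, Ifng, Tbx21, Il12rb2, Il18rap, Il4, Il5, Il13 and Gata3 wherever measured, up to 4 called members of each list whose interval bound nearest to 1 was farthest from 1, and the 5 lower and 5 higher genes by the same measure over all genes. For binding it named the 10 regions with the highest lower bound and, for each fixed gene, the region with most WT reads. Genes named outside it are members of small counts or overlaps and were chosen after their values were seen. The alternatives were scaling by total reads, scaling by an intensity trend, keeping all reads, minimums of 50 reads and of none, no minimum fold, another counting region (1000 bp around the start for H3K4me3, 2000 bp around it for H3K27me3, the part of the gene nearer its end for H3K36me3), a stricter window, a gap of 600 bp, no shift, background scaling in 10 kb bins, rabbit serum as control, a lower bound of 4, other overlaps and other distances to genes. Added after seeing the data were reads without a mismatch alone, genes with a mean of 50 or more reads over the H3K4me3 libraries, autosomes only, and lists matched on gene length. Each targeted gene was searched for the stretch with most WT reads and at most 1 read in the deficient libraries, with the search reversed as a control. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. No library was left out. The values of a few genes that the naming rule would name are not reported here.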

Results

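Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out in mouse CD4 T cells grown as T helper 1 (Th1) or T helper 2 (Th2) cells. STAT4, the transcription factor activated by interleukin 12, was precipitated from Th1 cells. STAT6, the factor activated by interleukin 4, was precipitated from Th2 cells. Each was precipitated from wild-type (WT) cells and from cells that lack the factor, here called STAT4-deficient and STAT6-deficient. From the same 4 kinds of culture, 3 histone modifications were mapped: H3K4me3, found at active promoters, H3K27me3, a Polycomb mark of repressed genes, and H3K36me3, which accumulates over transcribed gene bodies. Normal rabbit serum was used on WT Th2 cells as a control without a specific antibody. The series held 17 libraries in 17 groups with 1 library each, so no value has a replicate error, no difference has a replicate check, and each comparison is between libraries rather than conditions. Nuclear reads counted once per position and strand numbered from 5402414 in the rabbit serum library to 12075444 in the H3K27me3 library of STAT6-deficient Th2 cells. The STAT4 libraries held 8976765 (WT) and 7450989 (STAT4-deficient) such reads, and the STAT6 libraries 7442723 (WT) and 8231419 (STAT6-deficient). In Th1 cells the WT and STAT4-deficient libraries held 5744783 and 5672894 reads for H3K4me3, 11025368 and 10522630 for H3K27me3, and 6222899 and 6277457 for H3K36me3. In Th2 cells the WT and STAT6-deficient libraries held 10654206 and 10233923 reads for H3K4me3, 11985351 and 12075444 for H3K27me3, and 10464522 and 8996588 for H3K36me3. Intervals are exact 95% intervals (Clopper-Pearson for ratios and shares, Poisson for counts), covering counting error only. Positions are in the mm9 build.

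The Stat6 gene was the first item examined, since the labels say that it is disrupted in the STAT6-deficient cells. A stretch of 2263 bp within it, chromosome 10, 127092461 to 127094723, which overlaps 4 exons, held 1 read in the 3 STAT6-deficient histone libraries and 73 in the 3 WT Th2 histone libraries, a ratio of 0.0145 (95% interval 0.000362 to 0.0833). The stretch was picked by a search for missing reads, so the interval does not allow for the choice, and the same search in the opposite direction found 1 read in WT against 16 in STAT6-deficient cells at chromosome 10, 127082508 to 127082568. Over the whole gene the STAT6-deficient histone libraries held 1113 reads against 858, so the loss was limited to part of the gene. In the STAT6 antibody libraries the stretch held 2 reads in STAT6-deficient and 7 in WT cells, too few to tell apart. For Stat4 the search found no comparable stretch. It took the stretch with most WT reads among those with at most 1 deficient read, not the longest one. In the Th1 histone libraries this was 138 bp of intron, with 1 STAT4-deficient read against 15. A search in the opposite direction found a stretch with 1 read in WT against 13. In the STAT4 antibody libraries the 138 bp held 0 reads in STAT4-deficient and 6 in WT cells, with overlapping intervals (0 to 3.69 and 2.20 to 13.1). The whole Stat4 gene held 3182 reads in the STAT4-deficient and 3633 in the WT Th1 histone libraries. The Stat4 label could therefore not be checked from the reads of the gene itself.

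The STAT4 libraries addressed where STAT4 binds in Th1 cells. Ifng, which encodes interferon gamma, the cytokine that defines Th1 cells, held a STAT4-bound region on chromosome 10, 117877401 to 117884800, with 1137 reads in WT, 71 in STAT4-deficient and 16 in rabbit serum libraries, a WT to STAT4-deficient ratio of 13.3 (10.5 to 17.1). A region over the promoter of Il18rap, which encodes a subunit of the interleukin 18 receptor, held 574 against 28 reads (95% interval of the ratio 11.6 to 25.8). An intron of Il12rb2, which encodes a subunit of the interleukin 12 receptor, held a region with 144 against 1 read, a ratio of 120 (21.1 to 4753). Tbx21, which encodes T-bet, the Th1 lineage transcription factor, held 5 STAT4-bound regions. The one with most WT reads lay upstream of its start at -9755 bp and had a ratio of 7.99 (3.86 to 19.2). Stat4 itself held an intronic region (84 against 3 reads, ratio 23.2, 7.68 to 115). Gata3, the Th2 lineage transcription factor, held an intronic region on chromosome 2, 9788801 to 9789600, with a ratio of 8.20 (3.96 to 19.6). No STAT4-bound region was found in or within 10 kb upstream of Stat6, Il4, Il5 or Il13.

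In all, 14917 STAT4-bound regions were kept from 50249 candidates, and 122 were called with the WT and STAT4-deficient libraries swapped, 0.818% of that number. The swap does not count false regions that come from stronger enrichment of the WT library. The STAT4-bound regions had a median length of 400 bp, covered 7975600 bp (0.312% of the genome), and held 13.3% of the reads of the WT library, 1.27% of the STAT4-deficient and 1.44% of the rabbit serum library. The median ratio was 10.4 where the STAT4-deficient library had reads, and 2184 regions had none. Of all regions, 10693 (71.7%) also had at least a 2-fold lower bound over rabbit serum. That library came from WT Th2 cells, so it does not measure the background of Th1 chromatin. Promoters held 19.8% of the regions against 4.53% of shuffled ones, introns 36.9% against 33.9%, exons 1.82% against 2.27%, and intergenic sequence 41.5% against 59.3%. The 10 regions with the highest lower bounds included 1 beside Slc12a3 on chromosome 8, 96846801 to 96847400 (362 against 1 read, ratio 300.5, 53.6 to 11900.3). Others of the 10 lay at the promoter of Atp6v0d2 (327 against 1 read), in an intron of Rbl1 (290 against 1 read), in an intron of Dera (276 against 1 read), nearest to Ysk4 (312 against 1 read), nearest to Ffar3 (296 against 1 read) and nearest to Prl5a1 (267 against 1 read). A region nearest to Il6st, which encodes the gp130 cytokine receptor subunit, lay at -68016 bp from its start and held 590 against 5 reads, a ratio of 97.9 (41.7 to 303). The region nearest to Jarid2, a component of Polycomb complexes, held 434 against 3 reads (ratio 120, 40.8 to 585). The region beside Zfp318 had 186 reads in WT and 0 in the STAT4-deficient library, at least 51.5-fold more against a floor of 3 reads.

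**Figure D1:**
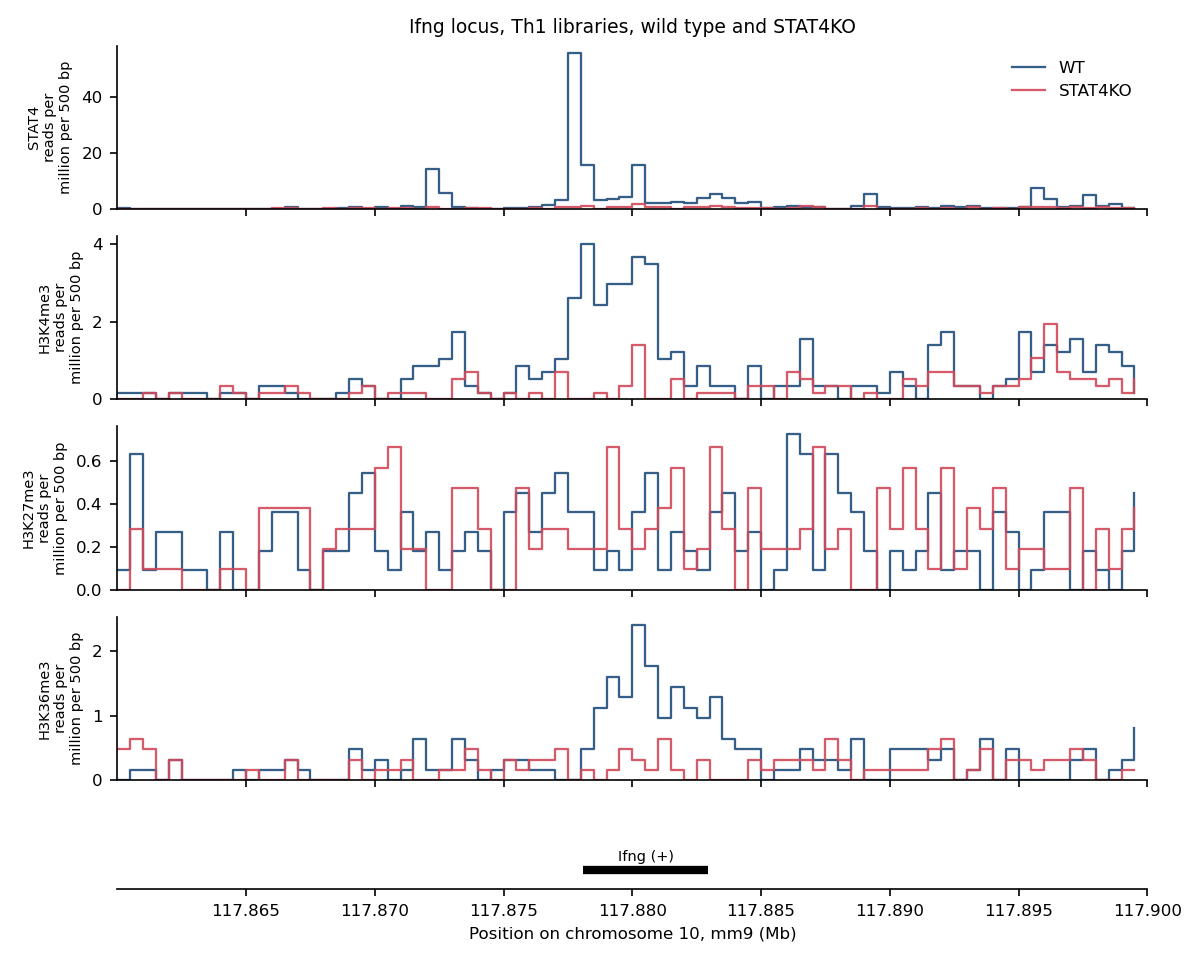
Reads per 1000000 reads in bins of 500 bp (vertical axes) along chromosome 10 around Ifng (horizontal axis, position), for STAT4, H3K4me3, H3K27me3 and H3K36me3 in WT and STAT4-deficient Th1 libraries. The highest STAT4 bin reached 55.5 in WT and 1.74 in the STAT4-deficient library, and the highest H3K36me3 bin 2.41 and 0.637, each pair at different positions.

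The STAT6 libraries addressed where STAT6 binds in Th2 cells. Il4, which encodes interleukin 4, the cytokine that drives Th2 cells, held an intronic STAT6-bound region on chromosome 11, 53418801 to 53419600, with 95 reads in WT, 23 in STAT6-deficient and 14 in rabbit serum libraries, a WT to STAT6-deficient ratio of 4.57 (2.87 to 7.55). Gata3 held a region over the same intronic windows as the STAT4 one, with 77 against 23 reads and a ratio of 3.70 (2.30 to 6.18). Stat4 held an intronic region on chromosome 1, 52133401 to 52133800, with 97 against 2 reads and a ratio of 53.6 (14.5 to 449). At Il5, which encodes interleukin 5, a window near the start held 9 reads in WT and 0 in the STAT6-deficient library, at least 3.32-fold more, but the rabbit serum library also held 9 reads there. No STAT6-bound region was found in or within 10 kb upstream of Stat6, Ifng, Tbx21, Il12rb2, Il18rap or Il13.

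In all, 7726 STAT6-bound regions were kept from 42294 candidates, with 37 called when the libraries were swapped (0.479%). Their median length was 400 bp, and they held 6.74% of the reads of the WT library, 0.834% of the STAT6-deficient and 0.672% of the rabbit serum library. The median ratio was 9.32 where the STAT6-deficient library had reads, 1142 regions had none, and 5553 (71.9%) also had at least a 2-fold lower bound over rabbit serum. Promoters held 12.1% of the regions against 4.36% of shuffled ones, introns 39.5% against 34.1%, exons 1.86% against 1.85%, and intergenic sequence 46.5% against 59.7%. Among the 10 regions with the highest lower bounds, an intronic region of Adamtsl3, which encodes a protein of the ADAMTS-like family, lay on chromosome 7, 89556601 to 89557200 (365 against 5 reads, ratio 80.7, 34.3 to 250.1). Introns of Plrg1 (257 against 3 reads, ratio 94.7, 32.1 to 462), Xpnpep1 (181 against 1 read) and Mbnl2 (158 against 1 read) held others. The remaining 6 had 0 reads in the STAT6-deficient library. They lay in introns of 1700025K23Rik (at least 63.0-fold) and 1700040L02Rik (42.0) and nearest to Zc3h12c (47.9), Rbm47 (45.0), 1110002B05Rik (42.8) and Vmn2r100 (40.9).

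**Figure D2:**
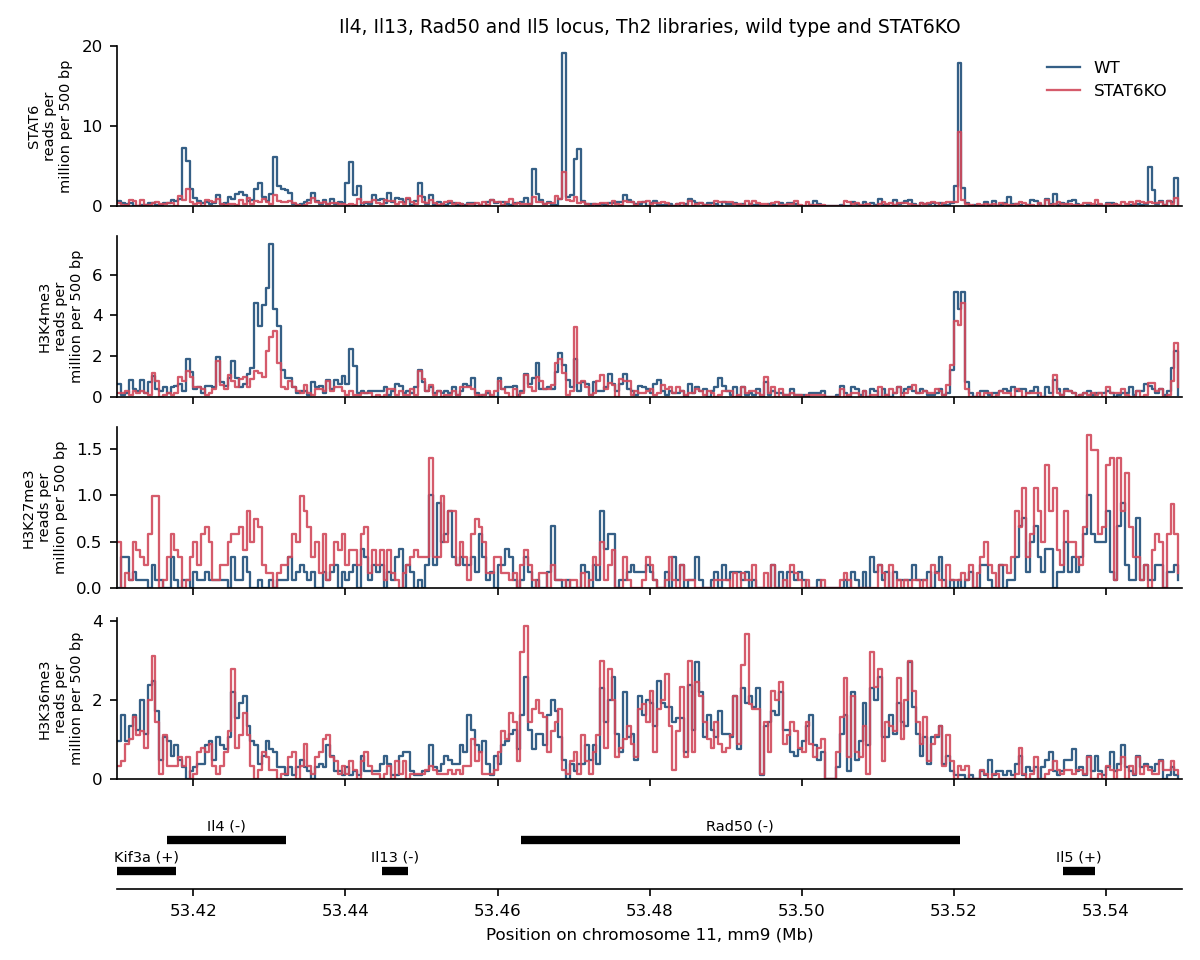
Reads per 1000000 reads in bins of 500 bp (vertical axes) along chromosome 11 over Il4, Il13, Rad50 and Il5 (horizontal axis, position), for STAT6, H3K4me3, H3K27me3 and H3K36me3 in WT and STAT6-deficient Th2 libraries. The highest STAT6 bin reached 19.1 in WT and 9.23 in the STAT6-deficient library, and the highest H3K4me3 bin 7.51 and 4.59, each pair at different positions.

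STAT4 and STAT6 shared many regions. Of the STAT6-bound regions, 2891 (37.4%, 36.3 to 38.5) overlapped a STAT4-bound region, against a mean of 46.5 and a maximum of 66 in 100 shuffles. Seen from the other factor, 2908 STAT4-bound regions (19.5%) overlapped a STAT6-bound one. With a lower bound of 4 for the ratio the shared share of STAT6-bound regions was 22.3%, and with equal numbers of top regions 24.9%. Among 22219 protein-coding genes, 6015 held a STAT4 region in the gene or within 10 kb upstream, 3091 a STAT6 region, and 2083 both, where 837 would have both if the lists were independent. The shuffles placed regions at random along each chromosome, and the product took no account of gene length. Both factors had more regions at promoters than shuffled ones did, and the part of these in the excess was not tested. Shared regions had more reads, with medians of 78 WT reads against 45 in unshared STAT4 regions and 65 against 30 in unshared STAT6 regions. Gata3 was the only one of the 10 fixed genes whose named region was the same for both factors. Stat4 had a named region for each at separate places in its introns.

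The comparison of STAT4-deficient with WT Th1 cells asked which histone marks change without STAT4. H3K4me3 fell over the promoter of Ifng, with 8 reads in the STAT4-deficient against 103 in the WT library, a scaled ratio of 0.136 (0.0573 to 0.278). It also fell at Nkg7, a cytotoxic granule protein (0.171, 0.0975 to 0.282), at the chemokine receptor gene Cxcr3 (0.351, 0.232 to 0.515), at Il21, which encodes interleukin 21 (0.180, 0.0699 to 0.392), and at Klrk1, which encodes the NKG2D receptor (0.206, 0.0532 to 0.578). H3K4me3 rose at Pdlim4 (4.47, 2.88 to 7.13) and at Oas2, an antiviral 2'-5' oligoadenylate synthetase (2.76, 1.75 to 4.41). Under scaling by total reads the log2 ratio of Oas2 was 0.67, less than 2-fold, and that of Pdlim4 1.35. The promoters of Tbx21 (0.787), Il12rb2 (0.621), Il18rap (0.542), Il4 (2.21), Il13 (1.35), Gata3 (1.09), Stat4 (0.953) and Stat6 (0.997) were not called. By the interval bound nearest 1, by which lowest and highest genes were ranked in every comparison, the 5 lowest genes also included Sbno2 (0.169), Ffar2, a receptor for short-chain fatty acids (0.158), and Plac8 (0.206), and the 5 highest also Vstm2a (8.47), Pla2g4f (10.1), Gm10134 (5.78) and Gm7120 (4.07).

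Of 13434 measured genes, 30 had lower and 69 higher H3K4me3. These values are relative to the median gene, because the STAT4-deficient library held 13.3% of its reads around gene starts against 22.3% in WT. Scaling by total reads moved the median by -0.79 on the log2 scale, a ratio of 0.578, and gave 2068 lower and 5 higher genes, the 30 lower ones among them, so that 5 of the 69 higher genes were kept. Scaling with an intensity trend gave 36 and 42. Without a mismatch were 66.4% of the reads of the WT and 57.6% of those of the STAT4-deficient library. With such reads alone, an alternative chosen after seeing the data, 19 of the 30 lower and 27 of the 69 higher genes were called again. This alternative also lowers the depth. The part of depth in the lost calls was not tested, here or for the other marks. Within 1000 bp of the start, 13 and 21 were called again. Of 27 measured Th1 genes, 4 were lower (Ifng, Nkg7 and Cxcr3 among them), none higher and 23 neither, and the median log2 ratio of -0.34 lay below the range of matched random lists (-0.14 to 0.11). The natural killer and CD8 T cell markers also lay below their range, with 1 of 5 lower (Klrk1) and a median of -0.40. The developmental Polycomb targets (median 0.42, none of 24 called, -0.37 under scaling by total reads) and the follicular helper genes (median 0.20, none of 8 called) lay above theirs. The medians of the Th2 genes (0.09), Th17 and Treg genes (0.11, with Il21 lower), naive and memory T cell genes (0.01), STAT feedback and cytokine signalling genes (-0.08), pan T cell genes (0.05), housekeeping genes (-0.01), interferon response genes (-0.15, with Oas2 higher) and myeloid cell markers (0.30) lay within theirs. The B cell and the erythroid and mast cell markers had 4 measured members each, too few for a range.

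H3K27me3 rose over Tbx21 without STAT4, with 123 reads against 47, a ratio of 2.62 (1.86 to 3.75). It also rose over the neighbouring Tbkbp1 (3.61, 2.48 to 5.38), Hlx, a homeobox factor of Th1 cells (2.26, 1.64 to 3.15), Plac8 (2.55) and Fes, a tyrosine kinase (3.06). The windows deposited as enriched held 9.82% of the reads of the WT and 7.59% of those of the STAT4-deficient library. Neither library had such a window at Tbx21, so the rise there was in counts outside the enrichment that the authors listed. In the window around the start the log2 ratio was 3.14 for Tbx21, 3.26 for Tbkbp1 and 2.09 for Plac8, against 1.38, 1.84 and 1.34 over the gene, and -1.39 for Tcf7 against -1.83. It fell over Ifngr2, which encodes a subunit of the interferon gamma receptor (58 against 315 reads, 0.184, 0.137 to 0.244), and over Tcf7, which encodes TCF-1, a factor of naive and memory T cells (0.280, 0.218 to 0.357). The other lowest genes were Tspan32 (0.265), Rnf141 (0.299) and BC106179 (0.224), and Gm10354 (4.50) was among the highest. Ifng (1.00, 0.636 to 1.57), Il12rb2 (1.24), Il18rap (1.19), Il4 (0.576), Il5 (0.797), Gata3 (0.951), Stat4 (0.880) and Stat6 (1.30) were not called. Of 17846 genes, 53 were lower and 15 higher, and scaling by total reads gave 40 and 21. Keeping all reads instead of 1 per position gave 57 lower and 63 higher genes, and the 63 included the 15. With reads without a mismatch alone 42 of the 53 lower and 8 of the 15 higher genes were called again, and in the window around the start 19 and 9. Of 25 Th1 genes, 2 were higher (Tbx21 and Hlx) and none lower, with a median of 0.17 inside the matched range (-0.14 to 0.19). Medians lay below the range for the Th17 and Treg genes (-0.39, 1 of 19 lower), the naive and memory T cell genes (-0.25, 2 of 15 lower, Tcf7 and Dapl1), the B cell markers (-0.25, none of 9 called) and the natural killer and CD8 T cell markers (-0.30, none of 9). Dapl1 had a ratio of 0.490, and in the window around its start a log2 ratio of -0.69, less than 2-fold. The Polycomb targets lay above the range (0.24, none of 31 called), and the 8 other lists lay within it.

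H3K36me3 over gene bodies fell at 4 of the fixed Th1 genes without STAT4. Il12rb2 held 557 reads against 1997 (0.285, 0.259 to 0.313), Il18rap 435 against 1210 (0.367, 0.328 to 0.410), Tbx21 87 against 226 (0.393, 0.303 to 0.506) and Ifng 15 against 81 (0.189, 0.101 to 0.331). It fell also at Hlx (0.138), Il21 (0.154) and Maf, a transcription factor of Th2 and follicular helper cells (0.301, 0.202 to 0.440). By the interval bound nearest 1, the lowest genes were Fes (8 against 160 reads, 0.0511, 0.0217 to 0.103), Rufy4 (0.104), Rassf4 (0.121), Dnahc3 (0.150) and Mgll, the monoacylglycerol lipase (0.175). It rose at Ifngr2 (4.03, 3.12 to 5.26), Pdlim4 (5.40, 3.36 to 9.06), D0H4S114 (5.37), Nav1 (3.87) and the interferon response genes Oas2 (3.67, 2.81 to 4.84), Rsad2 (3.21), Oasl2 (3.14) and Oas1a (2.96). Il4 (1.13), Gata3 (1.03), Stat4 (0.889) and Stat6 (1.00) were not called.

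Of 13786 genes, 118 had lower and 57 higher H3K36me3 in STAT4-deficient Th1 cells. With reads without a mismatch alone 93 and 34 of them were called again. Of 23 measured Th1 genes, 6 were lower and none higher, and the median of -0.65 was the farthest below its matched range (-0.12 to 0.16) among the lists. Smaller medians below their ranges were those of the follicular helper genes (-0.36, none of 8 called), housekeeping genes (-0.21, none of 18), Th2 genes (-0.16, Maf alone of 18 lower), STAT feedback and cytokine signalling genes (-0.16, none of 26) and pan T cell genes (-0.14, none of 19). The Polycomb targets lay above theirs (0.56, none of 9 called). Of 24 interferon response genes 4 were higher and none lower, and their median of 0.02 lay within the range, as did those of the 5 other lists with a range. The erythroid and mast cell markers had 3 measured members. Across marks, 12 genes were lower in both H3K4me3 and H3K36me3 where 0.208 would be if the calls were independent, among them Ifng, Il21, Plac8, Cxcr1, Cxcr2 and Icam1. Higher H3K27me3 met lower H3K36me3 at 5 genes (0.0704 if independent): Fes, Hlx, Plac8, Tbkbp1 and Tbx21. Lower H3K27me3 met higher H3K36me3 at 7 (0.184 if independent), among them Ifngr2, Pdlim4 and Rab4a. The numbers if independent were not adjusted for gene length or read number. Cxcr1, Cxcr2, Icam1 and Rab4a were picked after these values were seen.

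**Figure D3:**
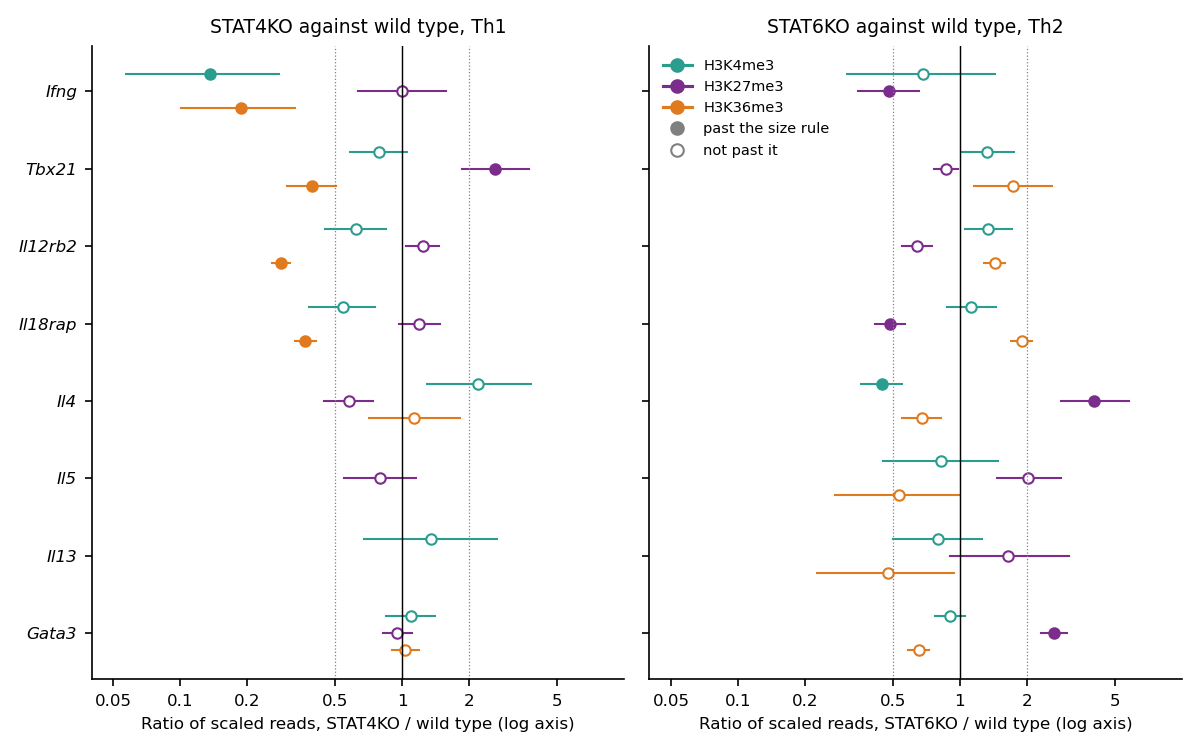
Ratios of reads in the deficient to the WT library with exact 95% intervals (horizontal log axis) for 8 fixed genes and 3 marks in both comparisons, with filled points past the size rule and dotted lines at 0.5 and 2. In STAT4-deficient Th1 cells the H3K36me3 points of Ifng (0.189), Tbx21 (0.393), Il12rb2 (0.285) and Il18rap (0.367) are filled, and in STAT6-deficient Th2 cells the H3K27me3 points of Il4 (4.03) and Gata3 (2.65) are filled above 2.

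The comparison of STAT6-deficient with WT Th2 cells asked the same of STAT6. H3K4me3 fell over the promoter of Il4, with 131 reads against 308, a ratio of 0.445 (0.360 to 0.548). It fell further at other cytokine genes, Il24 (0.123, 0.0899 to 0.164), Il10 (0.186, 0.137 to 0.249) and Il6 (0.239, 0.147 to 0.375), and at Ecm1 (0.355, 0.281 to 0.445), Il21 (0.330) and Havcr2, which encodes the inhibitory receptor TIM-3 (0.397). The lowest genes included Adamtsl3 (17 against 190 reads, 0.0936, 0.0534 to 0.154), Cyp11a1, the side-chain cleavage enzyme of steroid synthesis (0.150), and Tnfrsf8, which encodes CD30 (0.236). It rose at the interferon response genes Oas1a (2.63, 1.74 to 4.07) and Oas2 (2.03, 1.55 to 2.67) and at Rtp4 (2.35, 1.91 to 2.89), A530098C11Rik (3.14) and Gm17583 (4.01). Gata3 (0.898), Il5 (0.822), Il13 (0.796), Ifng (0.680), Tbx21 (1.33), Il12rb2 (1.34), Il18rap (1.13), Stat4 (1.37) and Stat6 (1.04) were not called.

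Of 15391 genes, 61 had lower and 7 higher H3K4me3 in STAT6-deficient Th2 cells. Within 1000 bp of the start the log2 ratio of Il4 was -0.94 and that of Rtp4 0.99, just under 2-fold. Of 29 measured Th2 genes, 6 were lower (Il24, Il10, Il6, Ecm1, Il4 and Ccr8) and none higher, and their median of -0.32 lay below the matched range (-0.09 to 0.07). The Th1 genes lay above their range (median 0.37, -0.10 to 0.09), although Havcr2 was lower and none of 27 was higher. The interferon response genes also lay above theirs (median 0.30, 2 of 26 higher). Medians of the Th17 and Treg (0.07), follicular helper (0.12), naive and memory (-0.03), STAT feedback (-0.04), pan T cell (0.05), housekeeping (-0.03), B cell (-0.01), myeloid (-0.08), erythroid and mast cell (0.02) and Polycomb target (0.15) lists lay within theirs, and 4 natural killer and CD8 T cell markers were measured, too few for a range.

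Without STAT6, H3K27me3 rose over 7 of 25 measured Th2 genes and fell over 8 of 27 Th1 genes, and most others were not called. The windows deposited as enriched held 33.5% of the reads of the STAT6-deficient and 23.6% of those of the WT library, and the part of this difference in the gene values was not tested. H3K27me3 rose over Il4 (166 against 43 reads, 4.03, 2.87 to 5.78), Gata3 (825 against 325, 2.65, 2.33 to 3.02), Il10 (440 against 55, 8.35, 6.30 to 11.3), Epas1, which encodes a hypoxia-inducible factor (4.08, 3.64 to 4.59), and Il24 (4.70). It fell over Ifng (60 against 131 reads, 0.478, 0.346 to 0.654), Il18rap (0.486, 0.416 to 0.567), Il18r1, the other interleukin 18 receptor subunit (0.307, 0.271 to 0.348), Havcr2 (0.306), the chemokine gene Ccl5 (0.316) and Lta, which encodes lymphotoxin alpha (0 against 20 reads, at least 6.39-fold lower). The transcription factor genes of naive and memory T cells Foxp1 (520 against 5050 reads, 0.107, 0.0980 to 0.118), Tcf7 (103 against 908, 0.118, 0.0956 to 0.145) and Bach2 (0.384) were lower, as were the regulatory T cell genes Ctla4 (0.249) and Ikzf2 (0.390), Il6ra (0.476), and the interferon response genes Oasl2 (0.322), Gbp5 (0.418), Mx2 (0.465) and Usp18 (0.466). In the window around the start alone, the log2 ratio of Il4 was 1.21 and of Il24 1.13, against 2.00 and 2.21 over the gene, that of Il10 also fell below its interval, and that of Epas1 was 3.44 against 2.03. There Foxp1 was at -5.35 and Bach2 at -0.23, less than 2-fold. Other extremes were Tmem65 (0.111), Spty2d1 (0.125) and Lrig1 (0.162) among the lowest and 5930403N24Rik (7.31), Six5 (6.16), Htr1b, a serotonin receptor gene (5.96), and Mgll (4.13) among the highest. Il5 (2.03, 1.46 to 2.85), Il13 (1.65), Tbx21 (0.869), Il12rb2 (0.640), Stat4 (0.683) and Stat6 (1.15) were not called.

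Of 17354 genes, 322 had lower and 255 higher H3K27me3 in STAT6-deficient Th2 cells, and scaling by total reads gave 393 and 183. In the window around gene starts 302 were lower and 78 higher, of which 116 and 51 were also called over whole genes. Of 27 measured Th1 genes 8 were lower and none higher (median -0.55, matched range -0.27 to 0.23), and of 25 Th2 genes 7 were higher and 1 lower, Tnfsf11 (median 0.54, -0.26 to 0.29). Medians below their ranges were those of the interferon response genes (-0.84, 4 of 23 lower), pan T cell genes (-0.70, Trat1 alone of 17 lower, 0.469), housekeeping genes (-0.57, none of 10 called), Th17 and Treg genes (-0.50, 3 of 19 lower), follicular helper genes (-0.44, none of 9) and naive and memory T cell genes (-0.34, 5 of 14 lower). With intensity-dependent scaling the housekeeping and follicular helper lists lay within their ranges, and the erythroid and mast cell markers lay above theirs. Medians above their ranges were those of the Polycomb targets (0.65, none of 31 called) and myeloid cell markers (0.55, none of 12). The B cell (0.22), erythroid and mast cell (0.33, with Klf1 higher at 2.69), natural killer and CD8 T cell (-0.33) and STAT feedback (-0.18) lists lay within theirs.

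H3K36me3 had 677 lower and 141 higher genes of 15626 in STAT6-deficient Th2 cells, and 524 and 208 with intensity-dependent scaling. Reads counted over genes made up 78.6% of the STAT6-deficient and 73.6% of the WT library. The part of this difference in the calls was not tested. By the interval bound nearest 1, the lowest genes were Adamtsl3, with 161 against 8692 reads, a ratio of 0.0203 (0.0173 to 0.0238), March10 (0.0464, 0.0359 to 0.0592), Rnf152 (0.0547), Epha2, an ephrin receptor gene (0.0609), and Tanc2 (0.0825). Among Th2 genes it fell at Maf (27 against 336 reads, 0.0882, 0.0573 to 0.131), Il6 (0.0784, 0.0307 to 0.168), Epas1 (0.155, 0.140 to 0.173) and Il10 (0.236). Il4 (0.673), Gata3 (0.651), Il5 (0.532) and Il13 (0.476, 0.228 to 0.940) were below 1 but not called. It rose at interferon response genes, Oas1a (149 against 12 reads, 13.6), Oas2 (587 against 55, 11.7, 8.88 to 15.7), Mx2 (8.55, 6.94 to 10.6) and Oasl2 (5.44), and at Ddx60 (5.25) and Ccdc164 (6.09). It rose also at Il2 (3.41, 2.21 to 5.43), Il18r1 (2.62, 2.33 to 2.95) and Tnf (2.32), and over the bodies of Btla (2.40) and Pdcd1 (2.04), which encode inhibitory receptors. Il18rap (1.90, 1.70 to 2.12), Il12rb2 (1.43), Tbx21 (1.73), Stat4 (1.20) and Stat6 (1.28) were not called.

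The list results for H3K36me3 in STAT6-deficient Th2 cells ran as follows. Of 27 Th2 genes 6 were lower and none higher (median -0.57, matched range -0.27 to 0.18). Of 25 interferon response genes 6 were higher and none lower (median 0.65, -0.24 to 0.22), and of 22 Th1 genes 3 were higher and Havcr2 lower (0.327), with a median of 0.31 above the range. The naive and memory T cell genes lay above theirs too (0.45), with Dapl1 (2.59) and Actn1 (2.53) higher of 15. The Polycomb targets lay below (-0.63, none of 11 called). The Th17 and Treg genes lay within their range (0.15), with Il1r1 (0.394), Il21 (0.389) and Ahr (0.486) lower. The natural killer and CD8 T cell markers lay within theirs (-0.52), with Gzma, which encodes granzyme A (0.235), and Zbtb16 (0.308) lower. The pan T cell genes (0.16, with Trat1 lower at 0.422), follicular helper genes (0.16, 2 of 8 higher), STAT feedback genes (0.14), housekeeping genes (0.07), B cell markers (-0.50) and myeloid cell markers (0.06) also lay within theirs. Of 3 erythroid and mast cell markers measured, Gata1 was higher (2.10), and in the alternative counting region its log2 ratio was 0.90, less than 2-fold. Ahr was at -0.96 under scaling by total reads, Pdcd1 at 0.99 under intensity-dependent scaling and Tnf at 0.88 in the alternative counting region, also less than 2-fold. Across marks, 42 genes were lower in both H3K4me3 and H3K36me3 (2.13 if independent), among them Il24, Il10, Il6, Il21, Cyp11a1 and Tnfrsf8. Lower H3K4me3 met higher H3K27me3 at 9 genes (0.967 if independent), among them Il4, Il10, Il24 and Tnfrsf8. Lower H3K27me3 met higher H3K36me3 at 16 (2.87 if independent), among them Il18r1, Mx2, Oasl2 and Rtp4, and higher H3K27me3 met lower H3K36me3 at 29 (8.08 if independent). The marks also moved the same way, with 31 genes lower in both H3K27me3 and H3K36me3 (14.1 if independent) and 4 lower in both H3K4me3 and H3K27me3 (1.13 if independent). The numbers if independent were not adjusted for gene length or read number, which can bring the same genes into both calls.

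**Figure D4:**
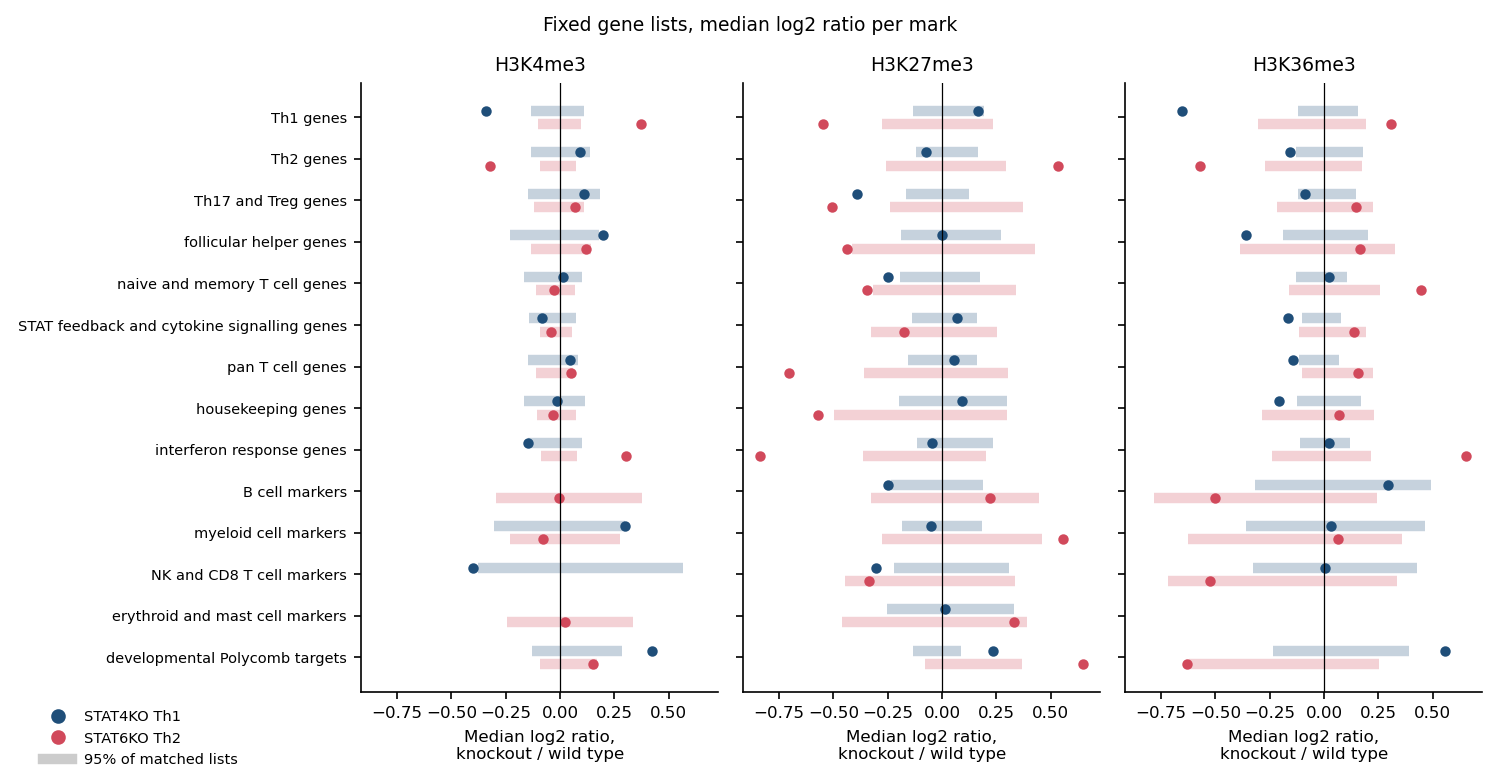
Median log2 ratio of the measured members of each fixed gene list (horizontal axis) for 3 marks in STAT4-deficient Th1 and STAT6-deficient Th2 cells, each relative to the median gene of its comparison, with pale bars for the 95% range of 10000 matched random lists. For H3K36me3 the Th1 genes lie at -0.65 in STAT4-deficient cells, and the Th2 genes at -0.57 and the interferon response genes at 0.65 in STAT6-deficient cells.

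Whether the changed genes carried a STAT region was then asked. Of the 30 genes with lower H3K4me3 in STAT4-deficient Th1 cells, 26 (86.7%) held a STAT4 region, where 35.0% would be expected from their lengths, and of the 69 with higher H3K4me3 12 did (17.4%, expected 36.7%). The 69 rest on scaling by the median gene, and 5 of them were kept with scaling by total reads, against all 30 lower genes. Expected shares here allowed for gene length alone, not for the level of the mark in WT cells. Genes called lower need reads in the WT library, and the regions were called in WT cells too. Part of the contrast between lower and higher genes may come from this. Of the 118 with lower H3K36me3, among them Ifng, Il12rb2 and Il18rap, 89 did (75.4%, expected 39.0%), and of the 57 with higher H3K36me3 21 (36.8%, expected 38.9%). For H3K27me3 these were 34 of 53 lower genes (64.2%, expected 32.4%) and 8 of 15 higher genes (53.3%, expected 18.7%). In STAT6-deficient Th2 cells, 44 of the 61 genes with lower H3K4me3 held a STAT6 region (72.1%, expected 17.5%), among them Adamtsl3, and 0 of the 7 with higher H3K4me3 (expected 11.8%). The shares were 41.9% of 322 genes with lower H3K27me3 (expected 20.1%), 28.2% of 255 with higher H3K27me3 (expected 9.73%), 39.9% of 677 with lower H3K36me3 (expected 23.6%) and 16.3% of 141 with higher H3K36me3 (expected 18.1%). Over all measured genes with a region the shifts were small. The median log2 ratio of STAT4-bound genes was -0.04 for H3K4me3 (5353 genes) and -0.04 for H3K36me3 (5309), each -0.03 from matched lists, and 0.00 for H3K27me3 (5626), 0.02 above them. The H3K27me3 shift lay within the range when lists were matched on gene length instead. For STAT6-bound genes the medians were -0.03 for H3K4me3 (2921 genes, -0.03 from matched lists), -0.13 for H3K27me3 (2892, -0.18) and -0.02 for H3K36me3 (2957, -0.07). With lists matched on gene length the H3K27me3 difference shrank to -0.04 and the H3K36me3 difference turned to 0.04.

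**Figure D5:**
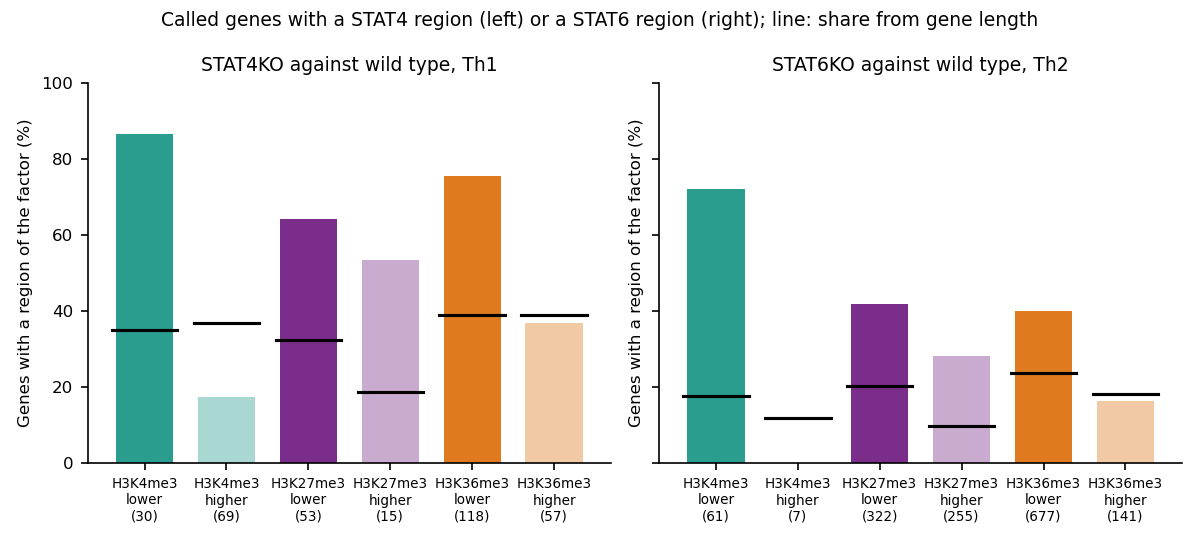
Percent of genes called lower or higher (vertical axis) that held a STAT4 region (STAT4-deficient Th1) or a STAT6 region (STAT6-deficient Th2), by mark, with the number of genes in brackets and lines at the percent expected from gene length. The bar for lower H3K4me3 stands at 86.7% in STAT4-deficient cells against 35.0% expected, and at 72.1% in STAT6-deficient cells against 17.5%. Of the 69 genes with higher H3K4me3 in STAT4-deficient cells, 5 were kept with scaling by total reads.

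WT Th2 cells were compared with WT Th1 cells to place the knockout values beside the difference between the lineages. Each of these WT libraries was also the reference of a knockout comparison. A deviation in 1 WT library moves both comparisons, so a likeness between them is not independent. The 6 Th1 histone libraries carried another kind of alignment record than the Th2 ones and still held repeated reads. Of their reads 49.0% to 66.4% lacked a mismatch, against 90.2% to 97.6% in the other 11 libraries. The libraries of the lineages thus also differed in processing, though whether the aligner differed is not stated. With reads without a mismatch alone, an alternative chosen after seeing the data, 96 of the 121 lower and 56 of the 74 higher H3K4me3 genes were kept, and 187 of the 204 lower and 906 of the 1080 higher H3K36me3 genes. The ratios of Ifng, Tbx21, Il12rb2, Il18rap and Il4 stayed inside their intervals for all 3 marks. Reads without a mismatch are fewer, above all in the Th1 libraries, and the part of this lower depth in the lost calls was not tested. With all reads kept, repeated ones being present in the Th1 libraries alone, 107 of the 121 lower H3K4me3 genes were called again. All 74 higher ones were among the 102 then called. For H3K27me3 436 of 449 lower and 350 of 385 higher genes were called again, and for H3K36me3 203 of 204 and 1075 of 1080. Differences in processing other than these were not tested. H3K4me3 was lower in Th2 at Ifng (0.109, 0.0642 to 0.178), Nkg7 (0.117), Cxcr3 (0.148), Ccl4, a chemokine gene (0.309), Tbx21 (0.361, 0.278 to 0.468), Il12rb2 (0.420) and Il18rap (0.441). It was higher at Il4 (308 against 27 reads, 6.43, 4.34 to 9.92), Il24 (6.81), Il6 (4.55) and Ccr8, a Th2 chemokine receptor gene (3.07), with A4galt (10.2), Adamtsl3 (7.65) and Cyp11a1 (7.43) among the highest. Gm4841 (0.0644), Samd3 (0.0862), Iigp1, an interferon-induced GTPase gene (0.164), Klrk1 (0.182) and Klrd1 (0.348) were lower too. Gata3 (1.22), Il5 (1.75), Il13 (1.18), Stat4 (0.924) and Stat6 (1.03) were not called. Of 14945 genes, 121 were lower and 74 higher, and scaling by total reads gave 162 and 62. Within 1000 bp of the start the log2 ratio of Tbx21 was -0.74, less than 2-fold. Of 27 Th1 genes 14 were lower (median -1.04), and of 29 Th2 genes 6 were higher (median 0.32), both outside their ranges. The interferon response genes (-0.23, 4 of 26 lower) and the natural killer and CD8 T cell markers (-0.69, 2 of 5 lower) lay below theirs, and the 10 other lists lay within. Of the interferon response genes, Gbp3 (-0.90), Mx1 (-0.95) and Irf8 (-0.97) were less than 2-fold on the log2 scale with reads without a mismatch alone.

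H3K27me3 was higher in Th2 over Tbx21 (568 against 47 reads, 11.1, 8.27 to 15.3) and its neighbour Tbkbp1 (11.3, 8.02 to 16.3), Il18r1 (5.75, 4.90 to 6.78), Hlx (3.69), Eomes, a T-box factor gene (3.10), Il18rap (2.93) and Ifng (2.88, 2.02 to 4.17). It was lower over Il4 (0.231, 0.161 to 0.324), Il24 (0.242), Ccr8 (0.282) and Epas1 (0.457), and over Ifngr2 (30 against 315 reads, 0.0878, 0.0583 to 0.128). Foxp1 (2.95, 2.78 to 3.12) and Tcf7 (2.73) were higher, and the pan T cell genes Ptprc (0.391) and Cd3d (0.286) lower. Of 17775 genes 449 were lower and 385 higher. With reads without a mismatch alone 211 were lower and 247 higher, of which 178 and 211 were among the former. The part of the lower depth in this was not tested. In the window around gene starts 202 were lower and 78 higher, of which 42 and 50 were also called over whole genes. The lower genes included the Y-linked Usp9y (0 against 140 reads, at least 50.6-fold), Uty (at least 36.9-fold), Zfy1 (10.8) and Kdm5d (9.04). Of the reads over 7 Y-linked genes in the 6 Th1 histone libraries, 12.8% lacked a mismatch, against 55.1% from the shares of those libraries. Of 27 Th1 genes 12 were higher and none lower (median 0.95, above the range), and of 27 Th2 genes 4 were lower and none higher (median -0.27, within it). The interferon response genes (0.65, 3 of 23 higher) and Polycomb targets (0.63, none of 31 called) lay above, the pan T cell genes (-0.40, 2 of 18 lower) below, and the 9 other lists within. The windows deposited as enriched held 23.6% of the reads of the WT Th2 and 9.82% of those of the WT Th1 library. The part of this difference in the gene and list values was not tested. With intensity-dependent scaling the pan T cell genes lay within. In the window around the start, Gbp5 had a log2 ratio of 0.22, Osbpl5 of 0.29, Il21 of 0.53, Il22 of 0.57 and Tcf7 of 0.95, each less than 2-fold, against 1.76, 1.98, 1.35, 1.28 and 1.45 over the gene. Ifng (1.00 against 1.51), Il18r1 (2.14 against 2.52) and Eomes (1.18 against 1.63) were also smaller there. Tbx21 (5.30 against 3.46), Foxp1 (2.32 against 1.56), Epas1 (-1.98 against -1.13) and Ifngr2 (-4.34 against -3.49) were larger there.

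H3K36me3 was lower in Th2 over Tbx21 (42 against 226 reads, 0.111, 0.0777 to 0.155), Ifng (0.133, 0.0748 to 0.223), Il12rb2 (0.188), Il18r1 (0.198) and Il18rap (507 against 1210 reads, 0.225 to 0.277), and over the interferon response genes Iigp1 (0.0546, 0.0347 to 0.0824), Mx2 (0.179) and Gbp2 (0.230). It was higher over Il4 (4.29, 3.03 to 6.22), Il5 (3.94, 1.53 to 12.9), Il13 (30 against 2 reads, 8.94, 2.27 to 77.2), Il6 (14.6), Il24 (8.73), Epas1 (16.7, 13.7 to 20.6) and Adamtsl3 (8692 against 185 reads, 28.0, 24.2 to 32.6), with Krt80 (27.3), Rnf152 (18.9) and March10 (16.5) among the highest. With intensity-dependent scaling the log2 ratio of Il5 was 0.93 and those of Tcf7 -0.76, Foxp1 -0.84 and Bcl6 -0.89, each less than 2-fold, against 1.86, -1.01, -1.10 and -1.03. Gata3 (1.35), Stat4 (0.546) and Stat6 (0.731) were not called. Of 15508 genes 204 were lower and 1080 higher, and with intensity-dependent scaling 246 and 804. Reads counted over genes made up 73.6% of the WT Th2 and 81.0% of the WT Th1 library, and the part of this in the calls was not tested. The same WT Th2 library was the reference for the STAT6-deficient one. Of 27 Th2 genes 13 were higher and none lower (median 1.16), of 23 Th1 genes 11 were lower and Havcr2 higher (-1.16), and of 24 interferon response genes 11 were lower and none higher (-0.92). The follicular helper genes (-0.65, Btla and Bcl6 lower of 8), naive and memory T cell genes (-0.58, 5 of 15 lower), pan T cell genes (-0.55) and housekeeping genes (-0.35) lay below their ranges. The myeloid cell markers lay above theirs (1.07), with Emr1 (3.44), Fcgr3 (2.83) and Sfpi1 (2.76) higher of 6. Of 3 erythroid and mast cell markers Cpa3 was higher (2.48), and the 5 other lists lay within their ranges.

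The windows that the authors deposited as enriched were counted at the fixed genes. At Ifng the files listed 15 windows of H3K4me3 and 14 of H3K36me3 in WT Th1 cells and 0 of each in STAT4-deficient cells. At Il12rb2 they listed 278 windows of H3K36me3 in WT and 12 in STAT4-deficient cells, and at Tbx21 31 and 7. Tbx21 held 63 windows of H3K27me3 in WT and 52 in STAT6-deficient Th2 cells, and 0 in both WT and STAT4-deficient Th1 cells, so the higher H3K27me3 counted there without STAT4 was not within windows that the authors listed. At Il4 they listed 0 windows of H3K27me3 in WT and 1 in STAT6-deficient Th2 cells. At Gata3 they listed 22 and 51, and 24 in WT and 39 in STAT4-deficient Th1 cells, where the counted ratio was 0.951. At Ifng and Il18rap there were 20 and 36 windows of H3K27me3 in WT Th2 and 0 of each in STAT6-deficient cells. For H3K4me3 there were 227963 windows in WT Th1 cells and 134443 in STAT4-deficient cells, with 114748 in both. WT and STAT6-deficient Th2 cells had 271747 and 285393 windows for H3K4me3, 405489 and 511884 for H3K27me3, and 741005 and 646689 for H3K36me3. In Th1 cells the WT and STAT4-deficient numbers were 184807 and 131962 for H3K27me3 and 544763 and 513542 for H3K36me3. The rabbit serum library had 19155.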

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

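The tests of weaker enrichment and of repeated reads in the H3K4me3 library of STAT4-deficient cells, and the test for male cells, were chosen after the result was seen, and the other tests before.

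Over gene bodies, 3 genes had H3K36me3 changed in opposite directions by the 2 deficiencies, which drew attention because the 27 genes lower in both and the 15 higher in both moved alike. Pdgfb, which encodes a platelet-derived growth factor chain, had a ratio of 0.279 (0.170 to 0.442) in STAT4-deficient Th1 and 2.41 (1.86 to 3.15) in STAT6-deficient Th2 cells. D8Ertd82e had 0.241 (0.207 to 0.281) and 4.06 (3.54 to 4.67), and Thbs1, which encodes thrombospondin, 3.95 (2.45 to 6.62) and 0.377 (0.221 to 0.621). Independent calls would give 1.05 genes of the first kind (lower, then higher) and 2.22 of the second, so such numbers arise without a relation between the deficiencies. The difference between the comparisons was not tested.

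Reads over 7 Y-linked genes, which no comparison was about, numbered from 90 to 339 in the 6 Th1 histone libraries and from 0 to 7 in the other 11. Male cells would bring reads without a mismatch at a level like that of the X-linked partners of these genes, yet the ratio was 0.0175 (0.0146 to 0.0207), with 136 reads against 7792, which argues against them. Of the Y-linked reads 12.8% lacked a mismatch where 55.1% would from the shares of the libraries, which is consistent with reads of other origin placed on the Y chromosome by the aligner of these 6 libraries. The STAT4 libraries of Th1 cells, which carry the other kind of alignment record, held 1 and 3 reads over these genes. The true origin of the reads was not traced, and a small share of male cells stays open.

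Under scaling by total reads, H3K4me3 around gene starts was lower in STAT4-deficient than in WT Th1 cells by -0.79 on the log2 scale at the median gene. Repeated reads were removed before counting, so their shares, 4.02% in the STAT4-deficient and 5.97% in the WT library, do not bear on it. A weaker enrichment of this library and a loss of H3K4me3 over all promoters without STAT4 cannot be told apart, as no second library and no spiked-in chromatin was there to part them. The list medians under this scaling, the highest being 0.774 for the Polycomb targets, restate the shift and decide nothing. The lower H3K4me3 at Ifng, Nkg7 and Cxcr3 was measured relative to this shift.

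Interferon response genes had higher H3K36me3 in STAT6-deficient Th2 cells, with 6 of 25 called and a median log2 ratio of 0.65. An intensity trend between the libraries does not account for it, since the median was 0.63 with intensity-dependent scaling, against a matched range of -0.21 to 0.21. Myeloid or B cells, which the sort for naive CD4 T cells would remove, would be expected to raise the H3K36me3 of their own genes. The higher of their list medians was 0.0638, that of 6 myeloid markers (matched range -0.63 to 0.36). The median of 9 B cell markers was -0.50 (-0.78 to 0.24). These ranges are wide and the size of rise to look for is not known, so a small share of such cells stays open. A loss of STAT6 bound at these genes could contribute, but this cannot be told apart here: 24% (6 of 25, among them Stat2, Igtp, Irf9, Gbp2 and Usp18) held a STAT6 region, inside the range of 0% to 28% in matched lists, and none of the 6 called genes (Oas1a, Oas2, Mx2, Oasl2, Ifit1 and Iigp1) was among them. Of these called genes, Oas1a, Oas2 and Oasl2 were also higher in STAT4-deficient Th1 cells, where the list median of 0.02 lay within its range. In the WT Th2 library, the reference here, 11 of 24 interferon response genes were lower than in WT Th1 (median -0.92). The absence of STAT6 itself, and any difference between the animals, stay open and untested.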

How the results depend on the processing

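Reads without a mismatch, genes with a mean of 50 reads, autosomes only and lists matched on gene length were chosen as alternatives after the results were seen, and the others before. Of the summary values 173 stayed the same, 35 moved, 2 became weaker and 1 reversed. Counts that stayed the same can hold other genes: the other counting region gave 46 genes with lower H3K27me3 in STAT4-deficient cells, of which 19 were among the 53. Of the list values 233 stayed the same, 4 became stronger and 3 weaker, and of the values of named genes 1911 stayed the same and 103 moved. No paired analysis was possible because each group held 1 library. Depth limits which genes reach 20 reads, from 13434 to 17846 of 22219, and its part in missed calls was not tested. Keeping all reads changed nothing in the STAT and Th2 libraries, which hold no repeated reads, and so tests nothing there. A lower bound of 4 can only remove regions and no minimum fold can only add genes, by construction, and for the rest the cause was not tested. A minimum of 50 reads also added calls, as for lower H3K27me3 in STAT6-deficient cells (338, of which 302 were among the 322). As reported, STAT4 had 14917 and STAT6 7726 regions. Lower and higher genes numbered 30 and 69 (H3K4me3) and 53 and 15 (H3K27me3) in STAT4-deficient cells, and 61 and 7, 322 and 255, and (H3K36me3) 677 and 141 in STAT6-deficient cells. Between Th2 and Th1 cells they numbered 121 and 74, 449 and 385, and 204 and 1080.

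With a lower bound of 4, STAT4 had 6280 and STAT6 2785 regions, with an overlap of 22.3%, and the same number of top regions gave 24.9%. Scaling by total reads gave 2068 lower and 5 higher genes for H3K4me3 in STAT4-deficient cells, and its myeloid markers, at 0.30 above matched lists, left their range. With intensity-dependent scaling this comparison had 42 higher genes, and its interferon response genes (-0.14) and myeloid markers (0.32) left their ranges. The same scaling brought the H3K27me3 values of the follicular helper (-0.28) and housekeeping genes (-0.35) in STAT6-deficient cells, and of the pan T cell genes between Th2 and Th1 cells (-0.28), within their ranges, and took the erythroid and mast cell markers (0.53, STAT6-deficient) out of theirs. Keeping all reads gave 106 higher genes for H3K4me3 and 63 for H3K27me3 in STAT4-deficient cells. A minimum of 50 reads gave 18 higher genes for H3K4me3 in STAT4-deficient cells and 80 lower ones between Th2 and Th1 cells. No minimum gave 482 higher genes for H3K4me3 and 24 for H3K27me3 in STAT4-deficient cells, and 15 for H3K4me3 in STAT6-deficient cells. No minimum fold gave 80 lower genes for H3K27me3 in STAT4-deficient cells, and in STAT6-deficient cells 11 higher for H3K4me3, 632 for H3K27me3 and 247 for H3K36me3. Between Th2 and Th1 cells it gave 668 higher for H3K27me3 and 484 lower for H3K36me3. The other counting region gave 31 higher genes for H3K4me3 and 32 for H3K27me3 in STAT4-deficient cells and 78 for H3K27me3 in STAT6-deficient cells. Between Th2 and Th1 cells it gave 43 higher for H3K4me3, and 202 lower and 78 higher for H3K27me3. Genes with a mean of 50 reads gave 14 lower and 25 higher for H3K4me3 in STAT4-deficient cells, 30 and 4 in STAT6-deficient cells, and 54 and 35 between Th2 and Th1 cells. Reads without a mismatch gave 26 higher for H3K27me3 in STAT4-deficient cells and 211 lower and 247 higher between Th2 and Th1 cells. The H3K27me3 shift of STAT4-bound genes lay within the matched range at 0 within 50 kb and at 0.00825 with lists matched on gene length. The H3K36me3 shift of STAT6-bound genes reversed to 0.0435 with the latter.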

Other observations

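The test of palindrome spacing was chosen before its result was seen, and the genes named here outside the naming rule were chosen after.

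Some genes lost or gained a mark in both deficiencies, in comparisons that share no library. The numbers for independent calls were not adjusted for gene length or read number, so part of an excess may come from these. H3K36me3 was lower in both at 27 genes, where independent calls would give 4.60, among them Maf, Il21, Id2 and Zeb2, which encode regulators of T cell differentiation, and Hmox1, which encodes a heme oxygenase. It was higher in both at 15 genes (0.506 if independent), among them the interferon-induced Oas1a, Oas2, Oasl2 and Ddx60, and Tlr7, a receptor of viral RNA. H3K27me3 was lower in both at 16 genes (0.956 if independent), among them Tcf7, Dapl1, Txk, a T cell kinase gene, Tnfsf4, which encodes OX40 ligand, and Bcl2l11, which encodes the cell death protein BIM. It was higher in both at the metallothionein genes Mt1 and Mt2 and at Hes7 and Ier3 (0.175 if independent). H3K4me3 was lower in both at Il21, Cxcr2, Sbno2 and Ctla2b (0.0710 if independent), and higher in both at Oas2 alone (0.0197 if independent), where the STAT4-deficient value fell under 2-fold with scaling by total reads (log2 0.67).

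A hypothesis was that STAT4 regions favour the palindrome of STAT proteins with 3 bases between its arms, and STAT6 regions the one with 4. In STAT6 regions the 4-base spacing was enriched over flanking sequence by 3.53 (3.35 to 3.71) and the 3-base spacing by 2.25 (2.13 to 2.38), a relative enrichment of 1.56 (1.45 to 1.69). In STAT4 regions the values were 1.07 (1.02 to 1.13) and 2.37 (2.28 to 2.46), a relative enrichment of 0.452 (0.425 to 0.481). Of the STAT6 regions 43.1% held a copy with 4 bases, against 12.9% of flanks, and 34.4% of the STAT4 regions held one with 3, against 15.4%. The values are consistent with the hypothesis, and they may also serve to tell the antibodies' targets apart, since a swap of the STAT4 and STAT6 labels would give the reverse.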
